A study of Rattus norvegicus with 6 samples.

How the data were processed

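The 6 arrays measured total RNA from the dorsolateral prostates of male ACI rats, an inbred strain, after 18 months on a high or a low corn oil diet. Corn oil is a vegetable fat rich in the omega-6 fatty acid linoleic acid. Each diet had 3 rats and each rat had its own array, so the replicates were separate animals. Per the labels, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of total RNA and hybridized to a short-oligonucleotide rat array of 8799 probe sets. The diet of each array was taken from its title. The title, the source name and the design of 3 rats per diet all place high corn oil replicate 3 in the high group, while its free-text description names the low diet. It was analysed as a high corn oil array, and counting it as low was an alternative.

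The deposited values were intensity values on a linear scale, 1 per probe set and array. MAS5 was the only tool named in the submitters' processing notes, and its version and settings were not given in the sources used here. MAS5 signal values are normally above 0, so the values at or below 0 are not that tool's usual output, and the algorithm that made them stays unknown. The deposited intensity values had been scaled by the authors before deposit: after removal of the highest and lowest 2% of probe sets, the mean was 2503 or 2504 on every array. From 18.6% to 23.1% of the values of an array were at or below 0, which points to subtraction of a background or mismatch signal, a step that no source used here describes. Detection calls were not used here, so an intensity near 0 could not be called present or absent. No 2 arrays shared more than 0.0572% of their values, so none was a copy of another. The number of arrays, 3 per diet, limits the precision of every comparison.

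Gene names came from the platform annotation and were updated through gene identifiers to the symbols of the GRCr8 rat annotation, which was used only for names and for gene order. Of the 8799 probe sets, 59 were controls, 7006 had 1 gene, of which 6985 were renamed through the identifier, 308 had several genes and 1426 had none. The named probe sets stood for 4736 genes. No gene was named from a probe set with several.

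Values below 0 were set to 0, a step added once negative values were seen, and then transformed as log2(value + pseudocount) with a pseudocount of 156.1, the median of all values (624.6) divided by 4. A fold change on this scale understates the change of dim genes. Arrays were not normalized further. Probe sets were tested if their mean value over the 6 arrays was at least 343, the 40th percentile, which left 5244 probe sets and 3162 genes. The diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, both directions tested), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The fit used all 6 arrays with no covariate.

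Gene lists were fixed before the data were examined, as were the test, the filter, the rule for named genes and most of the other settings. With 1 probe set per gene, the one with the highest mean value, 27 lists had at least 5 tested genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, were run beside it. A further 6 lists had too few tested genes and were only described. Array-level measures were compared with an exact permutation test in both directions, whose smallest possible p with 3 against 3 is 0.1.

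Named genes were chosen by 3 parts of a rule. First, the 12 higher and 12 lower genes with the largest fold past the threshold were named, with empty places filled, in order of unadjusted p, by genes whose 3 values of one diet all lay outside the 3 of the other. None passed, so all 24 places were filled in that way. Second, the 3 genes with the smallest p were taken from each list. In the last part, genes fixed in advance were named wherever they could be: Pbsn, Msmb, Odc1, Ptgs2, Igf1 and Mki67, of which Mki67 had no probe set named here, and a further gene that is not reported here.

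Other settings fixed in advance changed the pseudocount, the filter, the normalization between arrays, the intensity trend, array weights, a block on the replicate number, the group of high corn oil replicate 3, the summary of a gene's probe sets and the correlation in camera, and left out each array in turn. Added after the data were seen were a block on spike-in level, an asinh transformation that keeps values below 0, and quantile normalization without high corn oil replicate 1. The spike-in block came from the bacterial controls BioB, BioC and BioD, which are added to every hybridization in set amounts: arrays above and below the median signal formed 2 groups of 3.

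The limma and camera steps were tested on simulated data for the high against low corn oil comparison, in 5 runs on 5244 probe sets with 200 of them changed. A log2 change of 1 was recovered in 41.0% and a change of 2 in 88.6% of the changed probe sets, with at most 11 false calls in a run and 0 calls of the wrong sign. A shift of -0.60 planted in the fibroblast list, about that list's observed mean, was called in 5 of 5 runs, and 1 other list was called over all runs. The simulated noise was independent between genes. In the data the estimated correlation was 0.34 in the fibroblast, 0.37 in the smooth muscle and 0.42 in the ribosomal list. The runs therefore do not show how often camera at the preset correlation calls lists falsely in these data. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the plots.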

Results

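Expression was measured in the dorsolateral prostate, the rat prostate lobes often compared with the human peripheral zone, in 3 rats given much corn oil and 3 given little over 18 months of feeding. The comparison asks which transcripts differ in the prostate after long feeding of a diet rich in vegetable fat. The arrays had median values of 573, 710 and 646 under the high diet and 604, 591 and 632 under the low diet. The difference in medians, 33.7 units, gave p = 0.6 in an exact permutation test. The share of values at or below 0 averaged 21.6% ± 2.44 (SD, n = 3) under the high and 19.3% ± 0.883 under the low diet, with an exact permutation p of 0.3. For the log2 ratio of 3' to 5' Gapdh probe sets, a measure of RNA integrity, the exact permutation p was 0.7, and for the actin ratio it was 1. For the upper quartile and the 99th percentile of the values, the exact permutation p was 0.8 and 0.5. Adjusted over the 6 measures, every one of these p-values was at least 0.96. These tests compare diet means and do not show that the arrays were alike. The 99th percentile was 40930 and 46550 in high corn oil replicates 2 and 3. It was 57280 in high corn oil replicate 1 and 49650 to 56200 in the low corn oil arrays. At or below 0 were 23.1% and 23.0% of the values in high corn oil replicates 2 and 3, against 18.8% in replicate 1 and 18.6% to 20.3% under the low diet.

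High corn oil replicate 1 stood apart from the other high corn oil arrays. Its Spearman correlation across tested probe sets was 0.928 to 0.950 with the low corn oil arrays but 0.869 and 0.881 with high corn oil replicates 2 and 3. Correlations among low corn oil arrays ran from 0.927 to 0.954. All 7 probe sets for the bacterial spike-in controls BioB, BioC and BioD also split the arrays across diets: high corn oil replicate 1 and low corn oil replicates 1 and 2 were above high corn oil replicates 2 and 3 and low corn oil replicate 3, with ratios of means of 1.76 to 2.71. The 2 probe sets for the phage control Cre did not separate these arrays. The Gapdh 3' to 5' log2 ratio followed the same split, at 0.23, 0.29 and 0.24 against 0.12, 0.01 and -0.05. The actin ratio did not, at 0.21, 0.43 and 0.14 against 0.15, 0.25 and 0.08.

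**Figure D1:**
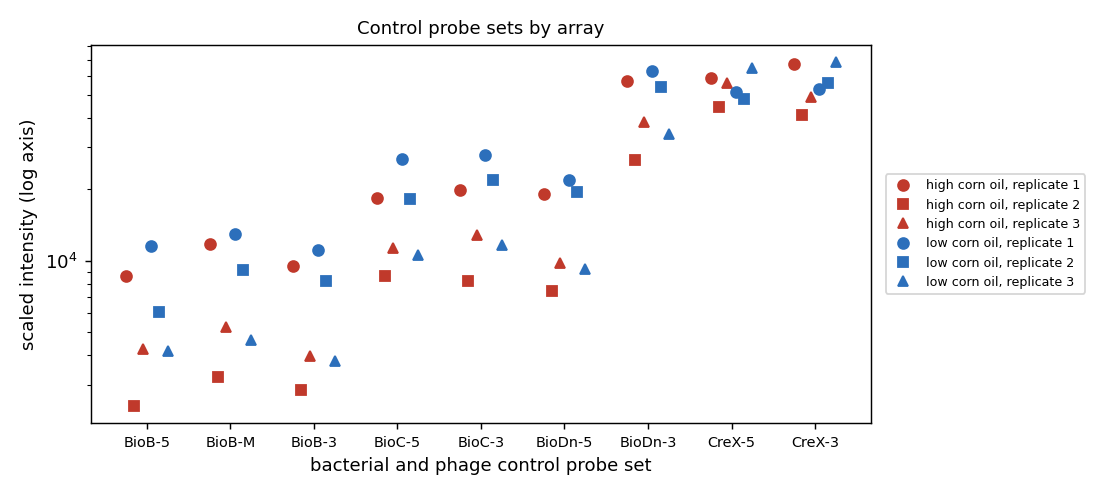
Scaled intensity on a log axis of 9 bacterial and phage control probe sets, with 1 point per array, coloured by diet and shaped by replicate number. On the 7 Bio probe sets high corn oil replicate 1 and low corn oil replicates 1 and 2 lie above the other arrays, and on the 2 CreX probe sets they do not.

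The 12 genes higher under the high corn oil diet with separate groups were led by Trappc14 and Gpc2. Nqo1, a quinone reductase and a classical target of the Nrf2 antioxidant response, averaged 6838 ± 408 (SD, n = 3) against 3509 ± 538, a log2 difference of 0.94 ± 0.16 (SE). Cyb5a, the cytochrome b5 that passes electrons to fatty acid desaturases, was 1.13 ± 0.26 higher, and Ndufv2, a subunit of respiratory complex I, 0.71 ± 0.16 higher. The clearest separation was in Trappc14, which encodes a subunit of a vesicle trafficking complex, at 5258 ± 202 against 2345 ± 178 and a log2 difference of 1.12 ± 0.14. Gpc2, a cell surface heparan sulfate proteoglycan, differed most among those of these 12 genes that were above 0 on all arrays, at 7194 ± 3787 against 884 ± 351 and 2.71 ± 0.46 on the log2 scale.

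Bhlha15, the transcription factor Mist1 of secretory cells, was 0.92 ± 0.16 higher in log2, and the endoplasmic reticulum chaperone gene Hyou1 was 0.63 ± 0.15 higher. Fblim1, which encodes a filamin-binding adhesion protein, was 1.32 ± 0.30 higher, Gabra5, a GABA receptor subunit gene, 1.80 ± 0.40, Camk2n1, an inhibitor of a calmodulin-dependent kinase, 2.21 ± 0.47, and the uncharacterized LOC102547955 1.53 ± 0.32. The last 3 were dim, with means of 953, 901 and 671 under the high diet, and Camk2n1 was at or below 0 on 1 low corn oil array. Casz1, a zinc finger transcription factor gene, averaged 1183 ± 890 under the high diet and was at or below 0 on all 3 low corn oil arrays, so no fold is given.

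The 12 genes lower under the high corn oil diet with separate groups were led by Cp and Ccnd2. Cp, the copper-carrying ferroxidase ceruloplasmin, averaged 20411 ± 1259 (SD, n = 3) against 33950 ± 2960, a log2 difference of -0.73 ± 0.13 (SE). The chemokine gene Cxcl14 averaged 11839 ± 3049 against 23855 ± 5902. The mast cell protease gene Mcpt1l1 differed by -1.62 ± 0.34 and Irf1, a transcription factor of the interferon response, by -0.89 ± 0.22. Ccnd2, which encodes the G1 cyclin D2, averaged 787 ± 145 against 1748 ± 120, a difference of -1.02 ± 0.21. Sparcl1, a matricellular protein gene, differed by -0.79 ± 0.19, the transcriptional repressor gene Zhx2 by -0.82 ± 0.19, and Rcn3, a calcium-binding protein of the endoplasmic reticulum, by -1.94 ± 0.40. Mrpl3, of the mitochondrial ribosome, differed by -0.89 ± 0.22, the phosphatase gene Ppp6c by -0.81 ± 0.20, and Atp1b1, a sodium pump subunit gene, by -0.54 ± 0.14. Apobec1, the editing enzyme of apolipoprotein B mRNA, averaged 721 ± 262 under the low diet and was at or below 0 on 2 of 3 high corn oil arrays.

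None of these genes passed the test with all 6 arrays and the filter. Over 5244 probe sets limma called 0 at the adjusted threshold, and the smallest adjusted p, shared by all 24 genes above, was 0.462. With no filter Trappc14 passed (limma adjusted p = 0.0325), with the same log2 difference of 1.12 but a standard error of 0.07 instead of 0.14. That setting adds dim probe sets with values set to 0, from which limma also estimates the error. The pass is therefore no added evidence for the gene. Without high corn oil replicate 1 limma called 14 of the 24, and with quantile normalization besides 12. At an unadjusted p under 0.05 there were 522 probe sets, 270 higher and 252 lower, where chance alone gives 262.2 on average, and 815 (15.5%) had groups that did not overlap, where chance gives 10%. With spike-in level as a block, limma again called 0, with 435 at an unadjusted p under 0.05. Leaving out high corn oil replicate 1 gave 214 probe sets past limma's adjusted threshold, 79 higher and 135 lower, and 1363 at an unadjusted p under 0.05. In that comparison both high arrays had low spike-in signal and 2 of the 3 low arrays high signal, so diet was largely mixed with spike-in level. Of the 214, 77 had groups that did not overlap over all 6 arrays, and in 123 high corn oil replicate 1 lay on the same side of the low mean as the other high arrays. Both counts use the same low arrays as the calls, and no chance share was computed for them. They are therefore no independent support from the array left out. The unadjusted count was 253 without high corn oil replicate 3, 296 without low corn oil replicate 1 and 274 without low corn oil replicate 2.

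**Figure D2:**
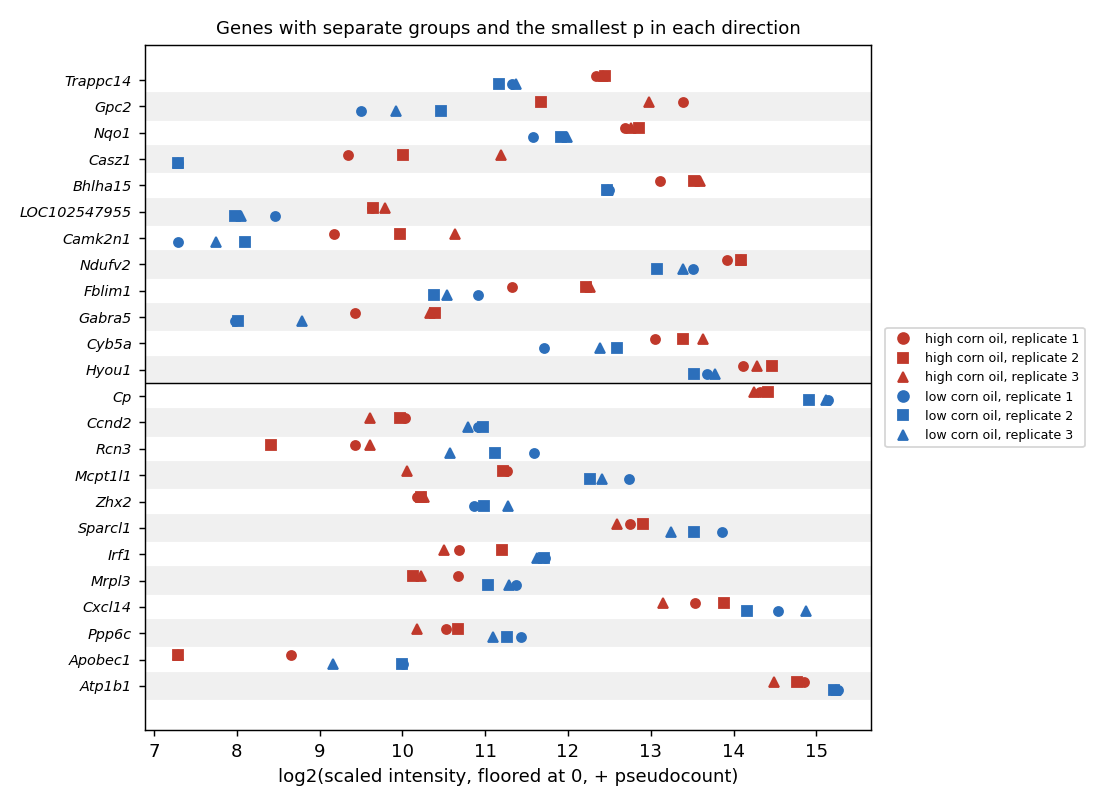
Log2 signal of the 24 genes with separate groups and the smallest p, 12 higher above the line and 12 lower below it, with 1 point per array; points on a value of 7.29 are values at or below 0. No gene passed the adjusted threshold (adjusted p = 0.462 in limma for each).

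Markers of fibroblasts fell as a list under the high corn oil diet. All 8 tested markers were lower, with a median log2 difference of -0.61 (camera adjusted p = 0.000107 in limma, and adjusted p = 0.544 with an estimated correlation). Thy1, a surface glycoprotein, was at -0.82 ± 0.23 (SE), the growth factor receptor gene Pdgfra at -0.97 ± 0.28, and Dcn, the collagen-binding proteoglycan decorin, at -0.60 ± 0.19. With Lum (-0.63 ± 0.21), these 4 genes passed limma's test when adjusted over the list alone, and 0 passed over all probe sets. Without high corn oil replicate 1, Dcn was at -0.77 (limma adjusted p = 0.0428), while its other tested probe sets were at 0.41, -0.46 and -0.57. Relative to the low corn oil mean, the list stood at -0.46, -0.58 and -0.76 in the 3 high corn oil arrays and at 0.35, -0.17 and -0.18 in the low ones. Its median was -0.43 among the 3 arrays with high spike-in signal and -0.56 among the 3 with low signal, and the camera adjusted p was 0.00137 with spike-in level as a block in limma.

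Macrophage and myeloid markers fell too, with 9 of 11 lower and a median of -0.31 (camera adjusted p = 0.00257 in limma, and adjusted p = 0.544 with an estimated correlation). The complement genes C1qb (-0.63 ± 0.18) and C1qc (-0.75 ± 0.22), made mainly by macrophages, the calcium-binding protein gene Aif1 (-0.76 ± 0.22) and the actin regulator gene Coro1a (-0.63 ± 0.20) passed limma's test adjusted over the list alone, and 0 over all probe sets. The medians were -0.59 and -0.27 among arrays with high and low spike-in signal, with a blocked camera adjusted p of 0.00137 in limma. Without high corn oil replicate 1 the list no longer passed (camera adjusted p = 0.159 in limma), although its mean moved little, from -0.31 to -0.26, and with array weights the adjusted p was 0.0639 and the mean -0.25. Probe sets of the leukocyte gene Ptprc went both ways, from -1.46 ± 0.32 to 0.31 ± 0.38.

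Genes of interferon response and antigen presentation also fell as a list, with 16 of 18 lower and a median of -0.26 (camera adjusted p = 0.00257 in limma, and adjusted p = 0.544 with an estimated correlation). The class II genes RT1-DMb and RT1-Ba were both at -0.71 ± 0.23 (RT1-Ba at -0.47 without low corn oil replicate 2) and the antiviral GTPase gene Mx1 at -0.40 ± 0.18. No member passed limma's test, over all probe sets or adjusted over the list alone. The medians were -0.44 and -0.11 among arrays with high and low spike-in signal, with a blocked camera adjusted p of 0.0202 in limma. Without high corn oil replicate 2 the camera adjusted p was 0.0541 in limma and the list mean -0.20, against -0.28 with all arrays. With quantile normalization without high corn oil replicate 1 the call was lost (camera adjusted p = 0.260 in limma) while the mean was -0.33. For the macrophage list the camera adjusted p in limma was then 0.466 with a mean of -0.29. Of these first 3 lists, none passed fry in limma (adjusted p = 0.232 for each).

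Smooth muscle markers and ribosomal protein genes fell as lists as well, and both calls were lost in several settings. Of 12 smooth muscle markers 9 were lower, with a median of -0.26 (camera adjusted p = 0.0226 in limma, and adjusted p = 0.731 with an estimated correlation). Among them the contractile genes Actg2 (-0.76 ± 0.28), Myl9 (-0.36 ± 0.14) and Cald1 (-0.56 ± 0.30) did not pass. Actg2 was at -0.47 without low corn oil replicate 1. Cald1 was at -0.85 without high corn oil replicate 2 and -0.35 without high corn oil replicate 3. Of 37 ribosomal protein genes 27 were lower, with a median of -0.13 (camera adjusted p = 0.0226 in limma, and adjusted p = 0.839 with an estimated correlation). Rpl17 was at -0.93 ± 0.26, Rpl30 at -0.89 ± 0.30 and Rpl39 at 0.71 ± 0.24, and none passed with all arrays. The smooth muscle list mean, -0.28 with all arrays, moved little where the call was lost with no filter (-0.25, camera adjusted p = 0.0865 in limma) or after quantile normalization (-0.27, 0.0655). It was smaller without high corn oil replicate 1 (-0.12, 0.780), without low corn oil replicate 1 (-0.15, 0.172), with high corn oil replicate 3 counted as low (-0.17, 0.0536), with array weights (-0.17, 0.417) and with the mean of a gene's probe sets (-0.21, 0.108). With quantile normalization without high corn oil replicate 1 it was -0.11 (0.919). The ribosomal mean, -0.13 with all arrays, was as large where the call was lost with no filter (-0.13, camera adjusted p = 0.0552 in limma). It was near 0 without high corn oil replicate 2 (-0.03, 0.768), after quantile normalization (-0.02, 0.977) and with quantile normalization without high corn oil replicate 1 (-0.04, 0.943). In between were the filter at the 60th percentile (-0.10, 0.0919), leaving out low corn oil replicate 3 (-0.10, 0.184) and counting high corn oil replicate 3 as low (-0.07, 0.0857). Without high corn oil replicate 1 the ribosomal call was instead stronger (median -0.28, camera adjusted p = 4.28e-05 in limma). Relative to the low corn oil mean, that array stood at 0.11 and the other high corn oil arrays at -0.33 and -0.17. The ribosomal median was 0.17 among arrays with high spike-in signal and -0.30 among those with low signal, and the blocked camera adjusted p in limma was 0.214 with a mean of -0.08. The blocked smooth muscle list gave a camera adjusted p of 0.00875 in limma. Its median, however, was -0.71 among arrays with high spike-in signal and -0.06 among those with low signal, so its fall lay mostly in the first group.

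**Figure D3:**
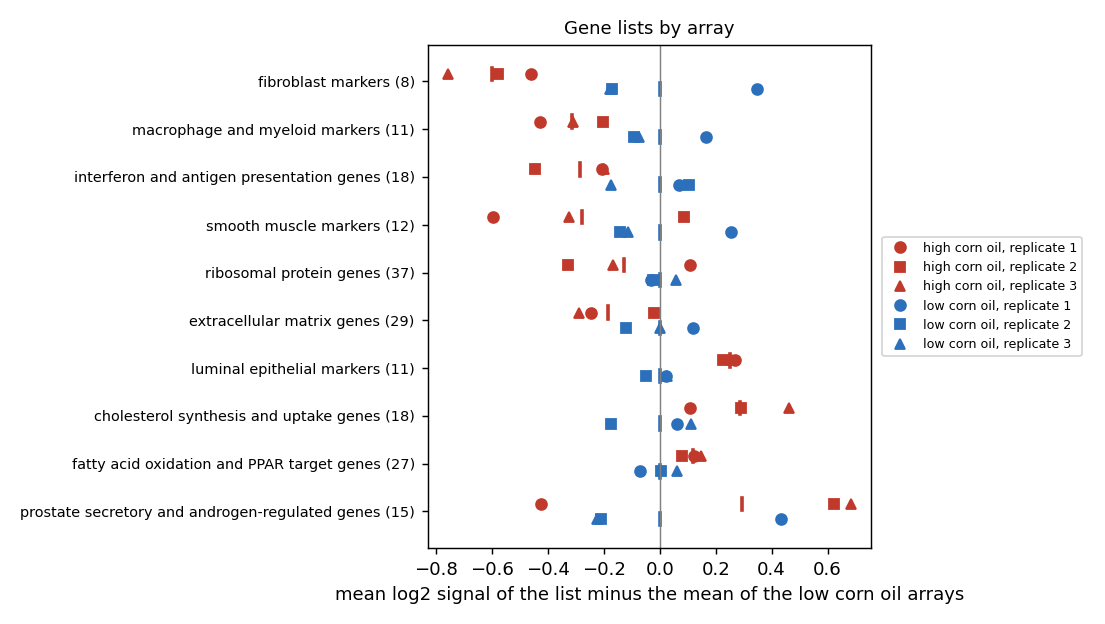
Mean log2 signal of 10 gene lists in each array relative to the mean of the low corn oil arrays, with the number of tested genes in brackets; points are arrays and vertical bars are diet means. The fibroblast list is at -0.46, -0.58 and -0.76 in the high corn oil arrays, while in the prostate secretory list high corn oil replicate 1 lies at -0.43 and the other high corn oil arrays at 0.62 and 0.68.

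Genes of lipid metabolism were mostly higher under the high corn oil diet, but none of their lists passed. Of 27 genes of fatty acid oxidation and PPAR response 19 were higher, with a median of 0.15 (camera adjusted p = 0.383 in limma), among them the acyl-CoA synthetases Acsl1 (0.60 ± 0.18) and Acsl3 (0.48 ± 0.19) and the carnitine palmitoyltransferase Cpt2 (0.41 ± 0.15). Of 18 genes of cholesterol synthesis and uptake 14 were higher, with a median of 0.25 (adjusted p = 0.144), led by Idi1 (0.75 ± 0.36), Mvk (0.97 ± 0.49, but 0.50 without low corn oil replicate 3) and Msmo1 (0.29 ± 0.15). Of 11 genes of fatty acid and triglyceride synthesis 7 were higher, with a median of 0.07 (adjusted p = 0.635), and fatty acid synthase Fasn (0.68 ± 0.21), malic enzyme Me1 (0.77 ± 0.27) and their regulator Srebf1 (0.69 ± 0.29, but 0.36 without low corn oil replicate 1) were the highest ranked. Eicosanoid genes went both ways: the prostacyclin receptor gene Ptgir was at -2.26 ± 0.61, the prostaglandin-degrading Hpgd at -2.12 ± 0.82 and the receptor gene Ptger3 at 0.60 ± 0.21, with 10 of 16 higher (median 0.10, mean -0.22, camera direction down, adjusted p = 0.854). Ptgir was below 0 on 1 high corn oil array, so its difference depends on the floor, and Hpgd was at -1.06 without low corn oil replicate 1. Ptgs2, the inducible cyclooxygenase, was at 0.21 ± 0.22 (limma adjusted p = 0.692), at 0.35 without high corn oil replicate 1 and at 0.14 without low corn oil replicate 1.

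Stress and energy genes gave single candidates and no list past the threshold. In the antioxidant and glutathione list 18 of 32 genes were lower, with a median of -0.09 (camera adjusted p = 0.903 in limma), and Nqo1 alone passed limma's test adjusted over the list alone (adjusted p = 0.0187), ahead of catalase Cat (0.87 ± 0.25) and Prdx3 (0.37 ± 0.20, but 0.19 without low corn oil replicate 1). Of 24 genes of the unfolded protein response and secretory pathway 14 were higher, with a median of 0.07 (adjusted p = 0.520), and after Hyou1 the chaperone genes Hspa5 (0.34 ± 0.16) and Calr (0.36 ± 0.17, but 0.19 without low corn oil replicate 2) ranked next. Of 28 oxidative phosphorylation genes 17 were higher, with a median of 0.04 (adjusted p = 0.635), and Ndufa9 (0.48 ± 0.17) and Atp5f1b (0.26 ± 0.14) followed Ndufv2. In the list of immediate early and heat shock genes Klf6, below 0 on 1 high corn oil array, was at -2.13 ± 0.65 (-1.35 without high corn oil replicate 3), Dusp6 at -1.23 ± 0.46 and the chaperonin gene Hspd1 at 0.48 ± 0.18 (0.31 without low corn oil replicate 1), with 13 of 25 higher (median 0.004, mean -0.11, camera direction down, adjusted p = 0.635). Without high corn oil replicate 1, Klf6 was at -2.76 (limma adjusted p = 0.0489) and Dusp6 at -1.81 (limma adjusted p = 0.0155).

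Growth and death genes showed no common direction. In the proliferation list 8 of 16 were higher (median 0.17, mean -0.02, camera direction down, adjusted p = 0.998 in limma); Ccnd2 alone passed limma's test adjusted over the list alone (adjusted p = 0.0232), while Ccnd3 was at 0.45 ± 0.17 and Pold1, a DNA polymerase subunit that was below 0 on 1 high corn oil array, at -1.36 ± 0.52 (-0.89 without high corn oil replicate 3). In the growth factor and IGF list 14 of 27 were higher (median 0.04, mean -0.03, camera direction down, adjusted p = 0.853), with the activin subunit gene Inhba at 1.29 ± 0.40, the hepatocyte growth factor receptor gene Met at -0.69 ± 0.24 and Pdgfra ranked first. Igf1 was at -0.77 ± 0.36 (limma adjusted p = 0.505), and at -0.38 without high corn oil replicate 3. Of 15 apoptosis and cell cycle inhibitor genes 10 were higher (median 0.07, adjusted p = 0.980), and the smallest p were those of Diablo (0.55 ± 0.24), Gadd45a (0.53 ± 0.35) and the lower Tnfrsf1a (-0.33 ± 0.30). Gadd45a was at 0.91 without high corn oil replicate 1 and 0.24 without high corn oil replicate 3. Tnfrsf1a was at -0.54 without the first, -0.03 without the second and -0.17 without low corn oil replicate 3. Of 19 genes of polyamine and of citrate and zinc metabolism 11 were lower (median -0.02, adjusted p = 0.980), with Oaz2 at 0.43 ± 0.16, citrate synthase Cs at 0.39 ± 0.16 and Mdh2 at 0.27 ± 0.13. Odc1, the first enzyme of polyamine synthesis, averaged 5445 ± 261 (SD, n = 3) against 5486 ± 865 (limma adjusted p = 0.998), and its log2 difference ran from -0.09 without low corn oil replicate 2 to 0.12 without low corn oil replicate 3.

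Pbsn and Msmb, among the brightest secretory genes, were lower than on every low corn oil array in high corn oil replicates 2 and 3 but not in replicate 1. Of 15 secretory and androgen-regulated genes 10 were higher, with a median of 0.13 and a mean of 0.29 (camera direction down, adjusted p = 0.980 in limma). Pbsn, the androgen-dependent secretory protein probasin, averaged 47117 ± 45441 (SD, n = 3) under the high and 80530 ± 2114 under the low diet, a log2 difference of -1.19 ± 0.57 (SE; limma adjusted p = 0.505). Msmb, the secreted microseminoprotein, averaged 49153 ± 21622 against 72929 ± 6781 (-0.65 ± 0.28; limma adjusted p = 0.501), and the protease inhibitor gene Cst3 was at -0.32 ± 0.14. Without high corn oil replicate 1, Pbsn was at -1.94 (limma adjusted p = 0.00591, range over all alternatives 0.00591 to 0.998) and Msmb at -0.98 (limma adjusted p = 0.0255, range 0.0222 to 0.998). Without high corn oil replicate 2 they were at -0.78 and -0.42. A second Pbsn probe set was at -0.28 ± 0.24 with all arrays and at -0.55 without high corn oil replicate 1, where it did not pass (limma adjusted p = 0.0598). Within the arrays of high spike-in signal the differences were 0.31 for Pbsn and 0.09 for Msmb, against -1.96 and -1.13 within those of low signal. Of 19 androgen-repressed and regression genes 13 were lower (median -0.14, adjusted p = 0.124), led by Mgp (-0.40 ± 0.13), Ctsb (-0.43 ± 0.16) and Igfbp2 (-0.43 ± 0.16, but -0.28 without high corn oil replicate 3). That list passed camera in limma without high corn oil replicate 3 (adjusted p = 0.0415) and with that array counted as low (adjusted p = 0.0250).

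Other tissue components gave lists that did not pass camera with all arrays and the settings fixed for the test. Luminal epithelial markers were higher in 7 of 11 (median 0.10, camera adjusted p = 0.238 in limma), led by the tight junction gene Cldn7 (0.71 ± 0.23), the mucin gene Muc1 (1.08 ± 0.41) and Epcam (0.32 ± 0.14). Extracellular matrix genes were lower in 17 of 29 (median -0.07, adjusted p = 0.0646), with Col1a2 at -0.53 ± 0.23 (-0.31 without low corn oil replicate 1) after Dcn and Lum. This list passed camera in limma with the filter at the 60th percentile (adjusted p = 0.0150), with the replicate block (0.0447), without high corn oil replicate 2 (0.0112) and without low corn oil replicate 2 (0.0128). Inflammation and NF-kB target genes were lower in 15 of 24 (median -0.14, adjusted p = 0.379), with Nfkb1 at -0.41 ± 0.15 and the osteopontin gene Spp1 at 1.35 ± 0.55 (0.70 without high corn oil replicate 2) after Irf1. Endothelial markers were higher in 4 of 5 (median 0.26, adjusted p = 0.635; Icam2 0.91 ± 0.90, Edn1 0.24 ± 0.29, Nos3 0.26 ± 0.35), though Icam2 was below 0 on 2 low corn oil arrays and its difference depends on the floor. Leaving out 1 array moved Icam2 between 0.35 (without low corn oil replicate 1 or 2) and 2.05 (without low corn oil replicate 3) and Edn1 between 0.13 (without low corn oil replicate 1) and 0.43 (without high corn oil replicate 1). Nos3 moved between 0.09 (without high corn oil replicate 2) and 0.53 (without high corn oil replicate 1).

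Lists of T and NK cell, nerve, adipocyte and skeletal muscle markers did not pass either. T and NK cell markers were higher in 5 of 7 (median 0.01, adjusted p = 0.903; Ctla4 0.61 ± 0.24, Lck -0.66 ± 0.35, Cd8b 0.68 ± 0.40). Lck was at -1.0 without high corn oil replicate 2 and -0.36 without high corn oil replicate 3. Cd8b was at 0.45 without high corn oil replicate 3 and 0.31 without low corn oil replicate 1. Nerve markers were lower in 4 of 6 (median -0.26, adjusted p = 0.424), with Ncam1 at -1.57 ± 0.47 (-1.0 without high corn oil replicate 3), Mag at 0.48 ± 0.28 (0.76 without high corn oil replicate 1, 0.29 without high corn oil replicate 2) and Nefl at -0.49 ± 0.33 (-0.22 without low corn oil replicate 1). Adipocyte markers were lower in 4 of 6 (median -0.27, adjusted p = 0.520), with Cfd at -1.08 ± 0.34, Adrb3 at 0.89 ± 0.38 and Lipe at -0.58 ± 0.48 (-1.14, -0.32 and -0.27 without high corn oil replicates 1, 2 and 3). Skeletal muscle markers were lower in 10 of 15 (median -0.16, adjusted p = 0.544), with Casq1 at 1.00 ± 0.45 (0.60 without low corn oil replicate 1), Pvalb at -0.53 ± 0.27 (-0.25 without low corn oil replicate 2) and Tnnc2 at -0.56 ± 0.35 (-0.92 without high corn oil replicate 2, -0.26 without high corn oil replicate 3). The skeletal muscle list passed camera in limma without high corn oil replicate 2 (adjusted p = 0.0173).

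Lists with fewer than 5 tested genes were described only. Of 4 basal epithelial markers 3 were higher, with Itgb4 at 0.53 ± 0.17, Krt5 at 0.27 ± 0.13 and Cav1, which is also abundant in muscle and endothelium, at -0.65 ± 0.20. Both tested B cell and plasma cell markers were higher (Cd79b 0.61 ± 0.39, Iglc1 0.50 ± 0.31). Mast cell markers split 2 and 2 (Srgn -0.59 ± 0.37, Cma1 -0.98 ± 0.71, Tpsab1 0.24 ± 0.28), as did red blood cell markers (Hbb -0.68 ± 0.30, Slc4a1 0.26 ± 0.25, Alas2 0.17 ± 0.24). Of 3 seminal vesicle markers, Svs3a was at 1.04 ± 0.40, Semg1 at -0.54 ± 0.34 and Svs4 at -0.02 ± 0.21. Leaving out high corn oil replicate 1 put Semg1 at -0.96 (limma adjusted p = 0.0313). It also put Cd79b at 0.97, Srgn at -0.93, Cma1 at -1.56, Tpsab1 at 0.50 and Slc4a1 at 0.44. All 4 tested genes of the ventral prostate list were lower on the log2 scale, but not in the same arrays. Scgb1d4 was at -0.68 ± 0.68, Scgb2a1 at -0.31 ± 0.58 and Scgb1d2 at -0.39 ± 0.92, though the mean intensity of Scgb1d2 was 28028 under the high and 26763 under the low diet. Pbsn, also in the secretory list, does not single out the ventral lobe. In the high corn oil arrays it read 99574, 19851 and 21926, opposite to Scgb1d2 at 3636, 36941 and 43508. The secretoglobins turned without high corn oil replicate 1, where Scgb1d4 was at 0.18, Scgb2a1 at 0.34 and Scgb1d2 at 0.75, while Pbsn was at -1.94. The smallest limma adjusted p among the genes of these lists was 0.462 with all arrays.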

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

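The spike-in block, the asinh transformation and quantile normalization without high corn oil replicate 1 were chosen after seeing the data. Past limma's adjusted threshold there were 0 probe sets, but 9 with no filter (8 of them with 3 arrays at or below 0), 203 with quantile normalization without high corn oil replicate 1, and 0 to 214 when 1 array was left out; 214 came without high corn oil replicate 1 and 0 without any other. The 522 at an unadjusted p under 0.05 became 347 with the filter at the 60th percentile, where fewer were tested, 1534 with array weights, 75 with high corn oil replicate 3 counted as low, 1337 with quantile normalization without high corn oil replicate 1, and 253 to 1363 when 1 array was left out. The 5 lists past the threshold became 3 with no filter, 3 with quantile normalization, 3 with array weights, 0 with an estimated correlation, 1 with quantile normalization without high corn oil replicate 1, and 3 to 6 when 1 array was left out. With the replicate number as a block, limma called 0 probe sets, 554 at an unadjusted p under 0.05 and 6 lists; same-numbered arrays deviated together with correlations of -0.05, -0.20 and 0.18, so the numbers were not taken as pairs. Directions turned with high corn oil replicate 3 counted as low for Gadd45a (-0.0379), Igf1 (0.00628), Lipe (0.0262), Tnfrsf1a (0.199) and Tnnc2 (0.0236), with the spike-in block for Nos3 (-0.0165), and for Odc1 with array weights (0.109) and when 1 array was left out (-0.0946 to 0.118). No list turned while past the threshold, and 51 of 564 list results turned while not past it. The 60th percentile filter left 22 named genes untested. Leaving out 1 array moved the log2 difference of 33 of 101 named genes by over 1.5 times. Except where a setting tested fewer probe sets or arrays, the cause was not tested. From 18.6% to 23.1% of an array's values lay at or below 0, which limits what dim genes can show.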

Other observations

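Of the tests given here, those of the spike-in batch, of the share of non-epithelial cells, of other splits of the arrays and of an equal change over a chromosome region were chosen only after the result was seen.

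Several abundant secretory transcripts fell into patterns that crossed the diets. These probe sets were singled out after their values were seen. Pbsn read 99574 in high corn oil replicate 1 and 19851 and 21926 in replicates 2 and 3, while the low corn oil arrays lay between 78113 and 82039. A second Pbsn probe set gave 61062, 32500 and 37102 against 49448 to 53756, and Msmb 73854, 33652 and 39953 against 66835 to 80234. Sbp, another secreted prostate protein gene, ran opposite in the high diet, with 1891, 45313 and 53056, and spread from 6801 to 39729 in the low diet. The ventral prostate secretoglobin gene Scgb1d2 likewise read 3636, 36941 and 43508 under the high diet and 15797 to 45781 under the low. Tissue kallikrein genes followed Sbp, with a Klk1c9 probe set at 578, 36704 and 44197 against 1374 to 15960, but kallikrein paralogs are close in sequence and their probe sets are uncertain. Others followed neither pattern: Tgm4 read 31002, 27652 and 13870 against 37737, 41267 and 5749, Svs4 28622, 32772 and 39172 against 34072, 26256 and 42692, and a Semg1 probe set 56554, 42256 and 48672 against 47952, 38903 and 57232, while another of Semg1 was nearer Pbsn, with 80278, 30689 and 36240 against 58912 to 75216.

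High corn oil replicate 1 resembled the low corn oil arrays. On 200 probe sets that separated high corn oil replicates 2 and 3 from each pair of low corn oil arrays, scaled from 0 at that pair to 1 at the high pair, it lay at 0.0191, 0.0406 and 0.138, where the held-out low array lay at 0.0512, -0.0235 and 0.285, so a mislabelled low-diet rat stays open. The array's fibroblast list (-0.46) lay below those of all 3 low arrays (-0.18 to 0.35), but that list was called with this array counted as high. The array's ribosomal list (0.11) lay above those of all 3 low arrays (-0.03 to 0.06), opposite to high corn oil replicates 2 and 3 (-0.33 and -0.17). A hybridization batch stays open as well, since the split by spike-in level gave 928 probe sets at an unadjusted limma p under 0.05, against 522 by diet, and low corn oil replicate 3 was the low array nearest the high pair. A probe-specific artefact was neither borne out nor excluded: of 119 other tested probe sets of the genes called without that array, 79.0% (exact 95% interval 70.6% to 85.9%) moved the same way, with a median of 0.257 of the called change, where a first version, corrected after its result was seen because it wrongly left out sets called themselves, gave 77.1% and 0.213. The interval treats these probe sets as independent, but they came from 79 genes on the same arrays, so it is too narrow. Each gene was compared with its called probe set of largest change, which lowers the median share. A diet response that the rat of high corn oil replicate 1 did not share, or shared in part, stays open as untested. A different mix of prostate lobes between the dissected samples was not tested either. The ventral prostate gene Scgb1d2 read 3636 in high corn oil replicate 1, below the 15797 to 45781 of the low corn oil arrays. Low corn oil replicate 1, however, had both Scgb1d2 at 45781 and Pbsn at 78113.

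The lower fibroblast, macrophage and antigen presentation lists were weighed in the same way. For the 3 lists the blocked camera adjusted p in limma was at most 0.0202, but at the preset correlation of 0.01. With an estimated correlation and no block it was 0.544 for each. The medians were negative within both spike-in groups (-0.43 and -0.56 for fibroblasts, -0.59 and -0.27 for macrophages, -0.44 and -0.11 for antigen presentation). Each group held only 1 array of one diet, so the spike-in batch as the whole cause was not excluded. Shared members are excluded by the make of the lists, fixed in advance, since 0 tested genes were in more than 1 of them. Whether the same cells carry more than 1 of these lists was not tested. A lower share of all non-epithelial cells stays open: luminal epithelial markers were higher by a mean of 0.25 ± 0.03 (SE over arrays, n = 3 per diet), but by a median of 0.10 with 4 of 11 lower and a camera adjusted p of 0.238 in limma, endothelial markers were 0.839 standard errors higher (0.32 ± 0.38, or 0.17 ± 0.25 without the dim Icam2), T and NK markers were at 0.09 ± 0.20, and nerve and smooth muscle markers at -0.32 ± 0.16 and -0.28 ± 0.24. An effect of diet on these cells or genes may equally underlie the lists, and histology was not used here.

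Trappc14 and Gpc2, the higher genes with the smallest p, were next to each other among the tested genes in chromosome order. A change of about the same size over the whole region is argued against: of the 10 nearest other tested genes 9 lay more than 2 standard errors below the 1.12 of Trappc14, with a median log2 difference of 0.22 and quartiles of -0.07 and 0.36. A smaller or uneven change over the whole region stays open, as 7 of the 10 were higher. Chance is undecided too: 16.1% of 100000 random picks of 24 of the 3156 placed genes held at least 1 neighbouring pair, while 2 genes drawn alone would be neighbours in 0.0630%, a value added after the first was seen, and the pair was noticed only after the 24 were listed. No explanation by diet was tested.

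The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By diet there were 522 probe sets at an unadjusted limma p under 0.05, reached by 2 of the 10 splits, the real one included, and the highest other count, 928, came from the split by spike-in level. By diet 5 lists passed, also reached by 2 of the 10 splits, the real one included, and the highest other count was 9. No split gave a probe set past limma's adjusted threshold.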
